A study of Mus musculus with 117 samples.

How the data were processed

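RNA from 117 mouse samples was labelled with biotin and hybridised to single-colour Affymetrix arrays. The values are log2 probe set signals as deposited by the authors, whose processing notes name RMA and Partek 6.6. RMA corrects the background, normalises the arrays to one another and summarises the probes of a set. Which settings were used, and whether any batch was corrected, the notes do not say. The 45141 probe sets of all 117 arrays were read on 1 scale, with values between 1.63 and 14.2 and array medians between 3.63 and 4.01, and they were used without further normalization or transformation. Arrays give no read depth. The upper quartile of each array, the 3' to 5' ratio of the control probe sets and the correlation of each array with the rest of its group (0.718 to 0.994) were computed as measures of quality.

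Samples were grouped by the tissue, tumour type and Prom1 status in the labels, which gave 12 groups of sorted normal cells and 7 tumour types. In stomach the number 2 occurs in the titles of 2 negative samples, so these are named by their codes, 239 and 298. The series mentions conditional mutants, but the labels do not state the genotype of each tumour, and it was not used here. An effect of genotype can therefore not be separated from tumour type or tumour state. The comparisons, tests, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

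Of the probe sets, 28898 had a single gene symbol, 551 had several and 15692 had none, and the last 2 kinds were left out. Symbols were brought up to date by Entrez identifier with a RefSeq gene table of mouse assembly GRCm38.p6. For each of 17097 genes the probe set with the highest mean over all samples was used. A gene entered a fit when its signal was above the median of the array in at least 3 of the arrays, which left 14081 genes for the sorted cells, 14663 for tumours against normal cells and 13456 for the tumour types.

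Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Prom1-positive minus Prom1-negative was tested over the 51 sorted samples, in each tissue, as the mean of 6 tissues and as the tissue by sort interaction. Tumour minus the mean of both sorted groups was tested over all 117 samples, in each of 5 organs, as their mean and as the organ by state interaction. The 7 tumour types were compared over the 66 tumours with the moderated F test. Data were handled with the data.table package, version 1.17.8, and figures drawn with Python 3.11 and matplotlib 3.10.9.

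Genes were named by a fixed rule: Prom1 and members of the lists; for a mean contrast the 10 largest rises and 10 largest falls among called genes with the same sign in every tissue or organ; for a single tissue or organ the 5 largest rises and 5 largest falls among called genes whose values did not overlap between the groups; and for a tumour type the 3 genes with the largest excess and no overlap with any other tumour. Predicted and clone-named genes were passed over. Genes named for recurring in several tissues were chosen after their values were seen.

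31 lists of cell type, tissue identity, stem cell, cell cycle, dissociation and pathway genes had been written from textbook knowledge; 404 of their 449 entries were measured. Each was tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a contrast, and also with fry. Another 15 genes of resident macrophages were listed after the pattern they were to test had been seen, but before their own values in the sorted cells were looked at.

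For similarity, Pearson r was computed across genes between each tumour and the mean of each sorted group of its organ. The mean difference between both correlations was tested by an exact two-sided permutation of the sort labels (35 to 330 relabellings), measured from the mean over relabellings, with adjustment over 5 organs.

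Alternatives covered the probe rule, the filter, repeated quantile normalization, median centring, robust and trended eBayes, array weights, the samples in the fit, the normal reference, a replicate block by title number, blocks of neighbouring sample codes, sample code range, each sample left out, and other measures of similarity. Leaving out arrays with an upper quartile under 6, using the upper quartile as a covariate and leaving out the stomach negative sample with code 239 were added after the data were seen. Title numbers did not mark pairs in the values: after group means were removed, 7 of 19 positive and negative samples with the same number correlated above 0.1, against 10 of 13 with neighbouring codes.

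The fits were tested on simulated data in which 100 genes were changed by 1 on the log2 scale. They recovered 93% of these genes in the mean of 6 tissues, 23% in prostate, 30% in lung, 16% in intestine, 30% in liver, 18% in stomach, 17% in uterus and 6% in the sort interaction. For tumours the share was 99% in the mean of 5 organs, 62% in prostate, 70% in lung, 74% in liver, 58% in stomach, 51% in uterus, 35% in the interaction and 79% among types. At a change of 0.5 the shares were 47% in the sort mean, 79% in the tumour mean, 20% among types, 0% or 1% in single tissues, 0% in the sort interaction, 8% to 21% in single organs and 3% in the organ interaction. In simulated lists camera called the shifted list (adjusted p = 3.01e-28) and 0 of 19 others. The simulated noise was drawn separately for each gene, so lists of correlated genes were not tested. Simulated tumours placed around the positive cells gave exact p values of 0.0179 in prostate, 0.00833 in lung, 0.0182 in liver, 0.0571 in stomach and 0.0286 in uterus. They were placed around the mean of the same positive arrays they were compared with, which favours the real labels. With no difference simulated, p was under 0.05 in 4 of 40 simulations in prostate, 3 in lung, 2 in liver, 2 in stomach and 0 in uterus.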

Results

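Gene expression was measured on single-colour Affymetrix arrays in 117 samples from C57BL/6 mice. Of these, 51 were normal cells that had been dissociated from 6 tissues and separated with anti-Prom1 MicroBeads into Prom1-positive and Prom1-negative cells. Prom1 encodes prominin-1, a glycoprotein of membrane protrusions that is widely used as a marker of stem and progenitor cells. The positive and negative cells numbered 3 and 5 samples in prostate, 3 and 7 in lung, 3 and 5 in intestine, 4 and 7 in liver, 3 and 4 in stomach, and 4 and 3 in uterus. The other 66 samples were tumours, frozen whole without dissociation or sorting: 14 bronchial papillary adenomas, 13 hepatocellular carcinomas, 11 gastric, 10 prostatic and 9 uterine adenocarcinomas, 6 squamous cell carcinomas of the skin and 3 B-cell lymphomas. The median of an array lay between 3.63 and 4.01 and its upper quartile between 5.05 and 6.53 on the log2 scale. The upper quartile was under 6 in 6 arrays, all of sorted cells: lung Prom1-positive sample 4, liver Prom1-positive samples 2 and 3, stomach Prom1-positive samples 2 and 3, and 1 of the stomach Prom1-negative samples numbered 2, the lowest at 5.05. The number of arrays limits the precision of every value. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between samples.

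**Figure D1:**
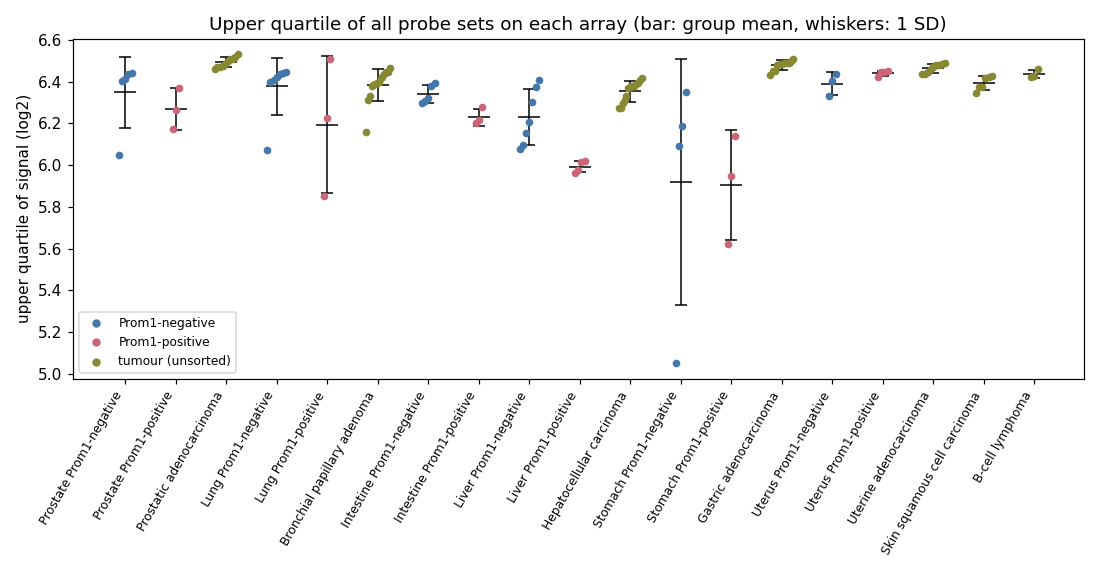
Upper quartile of each array (log2 signal) by group, with one point per array. The lowest array is a stomach Prom1-negative sample, at 5.05, and the tumour arrays lie between 6.16 and 6.53.

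The separation was made on the Prom1 protein, so the level of its transcript shows how far the sorted groups differed in Prom1 mRNA. Prom1 was higher in positive cells by 1.76 on the log2 scale in prostate (SE 0.41; 10.18 ± 0.44, SD, n = 3, against 8.42 ± 0.54, SD, n = 5; adjusted p = 0.00244). It was higher by 1.65 in stomach (SE 0.43; 11.85 ± 0.18, SD, n = 3, against 10.21 ± 0.78, SD, n = 4; adjusted p = 0.0189) and by 1.46 in uterus (SE 0.43; 11.37 ± 0.48, SD, n = 4, against 9.91 ± 0.54, SD, n = 3; adjusted p = 0.0173). In intestine the difference was 0.53 (SE 0.41, adjusted p = 1). In lung it was 0.01 (SE 0.38, 95% interval -0.77 to 0.78, adjusted p = 0.999) and in liver 0.23 (SE 0.35, adjusted p = 0.731), where the transcript was dim in both groups, at 3.17 ± 0.69 (SD, n = 4) and 2.94 ± 0.36 (SD, n = 7). The difference averaged over the 6 tissues was 0.94 (95% interval 0.61 to 1.27, adjusted p = 5.58e-05), and it differed between tissues (interaction adjusted p = 0.0322). The call in stomach was lost without any of positive samples 1, 2 or 3 (adjusted p = 0.0787, 0.0552 and 0.0529) or negative sample 1 (adjusted p = 0.0871). In uterus it was lost without positive sample 1, negative sample 1 or negative sample 2 (adjusted p = 0.0846, 0.133 and 0.0864). With all 117 samples in the limma fit Prom1 was called neither in the mean (adjusted p = 0.189) nor in prostate, stomach or uterus (adjusted p = 0.435, 0.532 and 0.628). A replicate block by title number lost the calls in prostate, stomach and uterus (adjusted p = 0.0818, 0.11 and 0.0812). Blocks of neighbouring sample codes lost the call in uterus (adjusted p = 0.114).

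**Figure D2:**
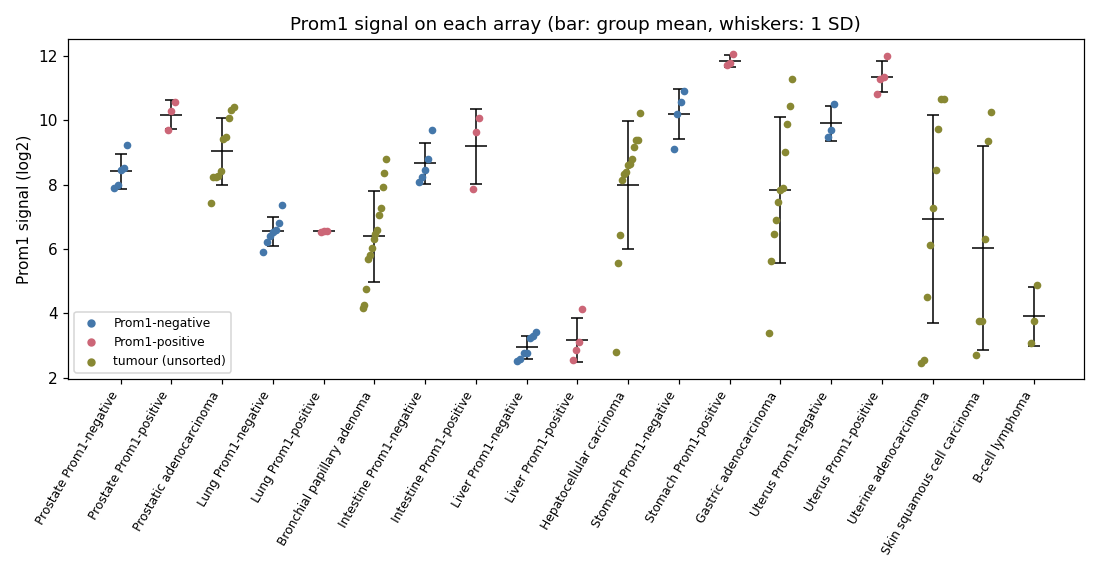
Prom1 transcript level (log2 signal) of each array by group, with the mean and 1 SD. Liver cells average 3.17 and 2.94 in the sorted groups and 7.99 in the hepatocellular carcinomas.

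Comparing positive with negative cells asks which transcripts accompany Prom1 on normal cells of the tissues in which the series looks for a stem cell origin of cancer. In a tissue where the dimmer group lay under the median of its arrays, as Vsig4 did in negative lung cells, its level can be background. The difference is then a lower bound. Averaged over the 6 tissues, T and NK cell genes were lower in Prom1-positive cells, and the largest falls included genes of immunoglobulin and haemoglobin chains. Gzmb, the granzyme B of cytotoxic lymphocytes, fell by 3.40 (SE 0.28, adjusted p = 4.27e-12), and Jchain, which links immunoglobulin A and M subunits, fell by 3.35 (SE 0.29). Cd3g, a chain of the T cell receptor complex, fell by 2.73 (SE 0.25). The haemoglobin chains Hbb-b2 (-3.39, SE 0.37) and Hba-a1 (-3.23, SE 0.39) fell too. So did Igk-V21 (-3.09), Iglv1 (-2.95), another immunoglobulin kappa variable gene (-2.66), Ms4a4b (-3.05) and Ctsw (-2.46). The genes that rose by the largest amounts in the mean, with a difference above 0 in all 6 tissues, included chemokines and receptors of macrophages (Ccl8 2.35, SE 0.41; the lectin Cd209f 2.25, SE 0.36; Ccl9 1.18; Trem2 1.16). They also included genes of epithelia (Wfdc15b 1.88, SE 0.19, adjusted p = 1.41e-09; Cldn2, a pore-forming tight junction protein, 1.66, SE 0.24; the transmembrane protease Hpn 1.08). Mia, the transporter Slco2b1 and Cbs, an enzyme that makes cystathionine from homocysteine, rose by 1.10, 1.10 and 1.07. Some of these differences were near 0 in a tissue, such as Trem2 in liver (0.0015) and intestine (0.13), Cd209f in liver (0.13), Ccl9 in intestine (0.10) and Mia in lung (0.03).

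In the same average, 12 of the 15 measured T and NK cell genes fell and none rose (13 fell adjusted over the list alone; median -1.53, camera adjusted p = 2.45e-22). So did 15 of 16 fibroblast and matrix genes (16 adjusted over the list alone; median -1.10, camera adjusted p = 7.68e-17). Of 11 mesenchymal transition genes 8 fell (8 adjusted over the list alone; median -0.66, camera adjusted p = 1.99e-05), and of 8 mesothelial genes 6 fell (7 adjusted over the list alone; median -1.02, camera adjusted p = 1.08e-08). These 4 calls held with an estimated correlation (adjusted p = 0.00592, 0.00871, 0.00871 and 0.0291). Among 19 epithelial genes 8 rose and none fell (11 adjusted over the list alone; median 0.41, camera adjusted p = 1.57e-05, adjusted p = 0.201 with an estimated correlation). Among 15 macrophage and monocyte genes 6 rose (8 adjusted over the list alone; median 0.66, camera adjusted p = 0.000148, adjusted p = 0.344 with an estimated correlation). Of 13 B cell genes 8 fell (8 adjusted over the list alone; median -0.89, camera adjusted p = 1.74e-06, adjusted p = 0.201 with an estimated correlation). The erythroid list was not called (2 of 9 fell, 2 adjusted over the list alone; median 0.02, camera adjusted p = 0.164). The list of 23 epithelial stem and progenitor genes was not called (camera adjusted p = 0.164, median 0.11), though 5 members rose (5 rose and 1 fell adjusted over the list alone): Lgr5 (0.78) and Ascl2 (0.78), markers of cycling intestinal stem cells, Sox9 (0.70), Hopx (0.79) and Prom1 itself. Smoc2, a matrix protein also made by intestinal stem cells, fell by 1.08.

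By limma, 1917 of 14081 genes differed in the average over tissues, 711 higher and 1206 lower in positive cells. Of them, 519 had the same sign in all 6 tissues, 200 higher and 319 lower. The direction of the whole set depended on scaling: 1168 genes were higher and 1138 lower after quantile normalization was repeated, and 2183 higher and 1264 lower with the upper quartile of the array as a covariate. With the number in the title as a replicate block 694 genes were called, and without the stomach negative sample with the lowest upper quartile the count was 3068.

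**Figure D3:**
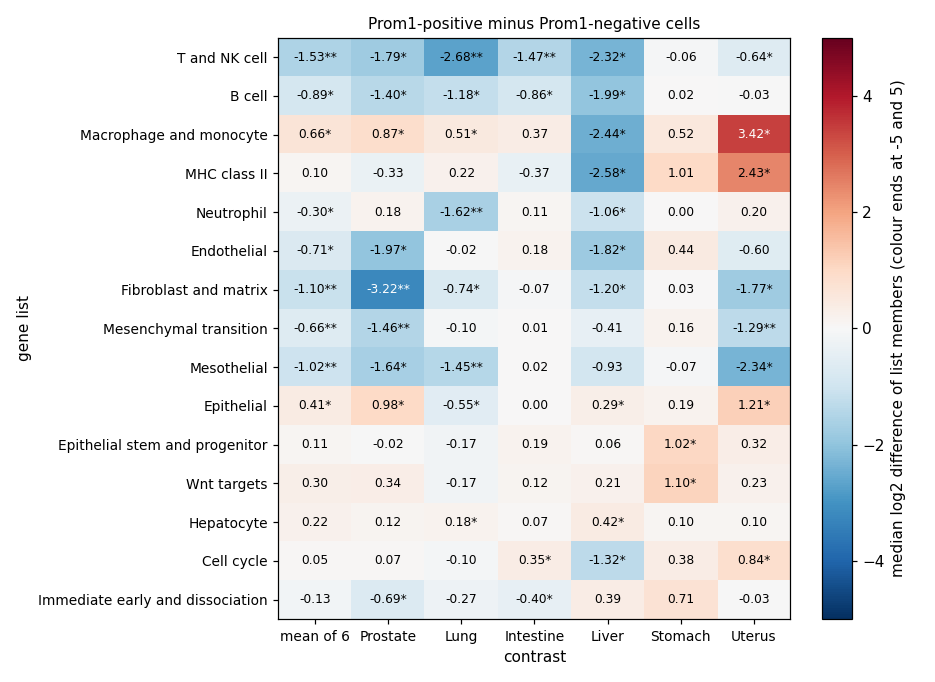
Median log2 difference, Prom1-positive minus Prom1-negative, of 15 fixed gene lists in the mean of 6 tissues and in each tissue; one asterisk marks a camera adjusted p under 0.05 and a second one marks lists that also pass with an estimated correlation. The T and NK cell median is -1.53 in the mean, and the macrophage and monocyte median is 3.42 in uterus and -2.44 in liver.

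In prostate, fibroblast, matrix and mesenchymal genes were lower in positive cells. Of 9 erythroid genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0912) and of 10 prostate epithelium genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0573), and neither list was called. Wfdc15b, a whey acidic protein family member, rose by 3.51 (SE 0.48; 11.40 ± 0.56, SD, n = 3, against 7.89 ± 0.48, SD, n = 5) and the secreted protein Odam by 3.26 (SE 0.34). Cyp4a12a, a fatty acid hydroxylase, rose by 3.13 (SE 0.56), Cwh43 by 3.12 (SE 0.65) and Mia by 2.89 (SE 0.42). Hbb-b2 (-6.34, SE 0.92) and Ccl21b, a lymphoid tissue chemokine (-5.99, SE 0.55), fell. Alas2, the erythroid enzyme of haem synthesis, fell by 5.93 (SE 1.07), and the matrix proteins Vit (-5.76, SE 0.45) and Clec3b (-5.68, SE 0.46) fell as well. Of 16 fibroblast and matrix genes 12 fell (15 adjusted over the list alone; median -3.22, camera adjusted p = 1.22e-21, adjusted p = 0.00251 with an estimated correlation). Of 11 mesenchymal transition genes 6 fell (9 adjusted over the list alone; median -1.46, camera adjusted p = 3.46e-08, adjusted p = 0.00123 with an estimated correlation). Endothelial genes fell in 6 of 15 cases (10 adjusted over the list alone; median -1.97, camera adjusted p = 6.14e-08, adjusted p = 0.223 with an estimated correlation). Epithelial genes rose in 3 of 19 cases (5 adjusted over the list alone; median 0.98, camera adjusted p = 8.35e-05, adjusted p = 0.223 with an estimated correlation). The Gapdh signal of positive prostate arrays was tilted further towards the 3' end (log2 ratio of 3' to 5' probe sets 0.997 ± 0.054, SD, n = 3, against 0.64 ± 0.14, SD, n = 5), and its effect on the calls was not tested. In all, 1294 genes differed, 452 higher and 842 lower. The split was 692 higher and 774 lower after repeated quantile normalization and 1025 and 966 with the upper quartile as a covariate. The number called was 656 without positive sample 2, 2424 without the arrays whose upper quartile was under 6 and 523 with the replicate block.

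In lung, several macrophage genes were among those that rose most in positive cells, and T and NK cell genes were lower. Vsig4, a complement receptor of resident macrophages, rose by 5.31 (SE 0.75; 8.57 ± 1.61, SD, n = 3, against 3.26 ± 0.72, SD, n = 7; adjusted p = 2.27e-05). It was followed by the lectin Cd209g (5.15, SE 0.91), the ficolin Fcna (5.06, SE 0.85), the chemokine Ccl24 (5.03, SE 0.76) and the folate receptor Folr2 (4.76, SE 0.77). Ms4a4b, a membrane protein of T cells (-5.0, SE 1.14), and Il2rb, a chain of the interleukin receptor of T and NK cells (-4.23, SE 0.52), fell. Gzmb (-4.21), Cd3g (-4.17) and Gzma (-4.10) fell as well. Of 15 T and NK cell genes 10 fell (10 adjusted over the list alone; median -2.68, camera adjusted p = 2.21e-29, adjusted p = 0.000901 with an estimated correlation). Among 13 neutrophil genes 6 fell (9 fell and 1 rose adjusted over the list alone; median -1.62, camera adjusted p = 5.5e-10, adjusted p = 0.025 with an estimated correlation). Among 8 mesothelial genes 2 fell (7 adjusted over the list alone; median -1.45, camera adjusted p = 1.41e-09, adjusted p = 0.025 with an estimated correlation). In the macrophage and monocyte list the complement genes C1qa, C1qb and C1qc rose (3.05, 3.32 and 3.53) and no member fell (5 rose adjusted over the list alone; median 0.51, camera adjusted p = 8.33e-06, adjusted p = 0.366 with an estimated correlation). The Actb signal of positive lung arrays was tilted likewise (1.05 ± 0.06, SD, n = 3, against 0.57 ± 0.11, SD, n = 7). In all, 212 genes differed, 55 higher and the others lower. The count was 526 without positive sample 1, 124 without positive sample 2, 120 without positive sample 4, 56 with the replicate block and 57 in a fit of the lung samples alone. With blocks of neighbouring sample codes 0.731% of the 14081 genes were called, against 1.51%. The call of Ms4a4b was lost without positive sample 2 or 4 (adjusted p = 0.0624 and 0.0722).

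In intestine, limma called 28 genes, all lower in positive cells (571 genes at an unadjusted p under 0.05), and they included blood and plasma cell transcripts. Hba-a1 (-5.68, SE 0.96) and Hbb-b2 (-5.15, SE 0.92) fell. So did the immunoglobulin light chain genes Iglv1 (-4.86, SE 0.81) and Igk-V21 (-4.48, SE 0.67) and another kappa variable gene (-4.47, SE 0.86). For Hba-a1 the levels were 6.42 ± 1.59 (SD, n = 3) and 12.10 ± 1.13 (SD, n = 5; adjusted p = 0.00107). The upper quartiles of positive intestine arrays were lower (6.23 ± 0.04, SD, n = 3, against 6.34 ± 0.04, SD, n = 5). Their Actb signal was tilted further towards the 3' end (0.98 ± 0.19, SD, n = 3, against 0.67 ± 0.17, SD, n = 5), and the effect of this tilt was not tested. Of 15 T and NK cell genes only the adaptor Lat fell over all genes tested (-2.15), with 9 falling adjusted over the list alone (median -1.47, camera adjusted p = 1.23e-19, adjusted p = 0.0129 with an estimated correlation). The count was 14 without positive sample 3, 68 without positive sample 2, 50 without negative sample 1 and 47 without negative sample 2. It was 46 without the arrays whose upper quartile was under 6, 2 in a fit of the intestine samples alone and 0 with the replicate block (limma, with 1.14% of 14081 genes at an unadjusted p under 0.05). The call of that kappa variable gene was lost without positive sample 3 (adjusted p = 0.0827), and that of Hbb-b2 when the probe sets of a gene were averaged (-2.17, adjusted p = 0.203).

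In liver, leukocyte, endothelial and cell cycle transcripts were lower in positive cells. Ccl5, a chemokine of T and NK cells, fell by 5.45 (SE 0.49; 4.53 ± 1.02, SD, n = 4, against 9.98 ± 0.88, SD, n = 7; adjusted p = 2.2e-10). Nkg7, a protein of cytotoxic granules (-4.95, SE 0.48), the neutrophil calcium-binding proteins S100a8 (-4.88, SE 0.79) and S100a9 (-4.67, SE 0.83), and Gzmb (-4.53, SE 0.59) fell as well. The genes that rose by the largest amounts were Pdilt (2.74, SE 0.36), a disulfide isomerase relative of the testis, the long noncoding RNAs Kcnq1ot1 (2.72, SE 0.44) and Lncpint (2.15, SE 0.43), the DNA demethylating enzyme Tet2 (2.24, SE 0.42) and Ankrd33b (2.15, SE 0.44). Members fell, and none rose, in 12 of 15 T and NK cell genes (median -2.32), 13 of 15 macrophage and monocyte genes (median -2.44) and 8 of 8 MHC class II genes (median -2.58). The same held for 10 of 15 endothelial genes (median -1.82), 7 of 10 interferon response genes (median -1.75) and 15 of 23 cell cycle genes (median -1.32). Adjusted over the list alone these falls numbered 12, 15, 8, 14, 8 and 16. The camera adjusted p values were 2.42e-10, 6.11e-08, 2.05e-07, 0.000589, 0.00019 and 2.13e-06, and all 6 calls were lost (adjusted p = 0.21, 0.291, 0.21, 0.433, 0.291 and 0.389 with an estimated correlation). None of the 18 hepatocyte genes passed (median 0.42, camera adjusted p = 0.0024, adjusted p = 0.389 with an estimated correlation). The arrays of positive liver cells had lower upper quartiles (5.99 ± 0.03, SD, n = 4, against 6.23 ± 0.13, SD, n = 7). Their Gapdh signal was tilted further towards the 3' end (log2 ratio of 3' to 5' probe sets 1.14 ± 0.04, SD, n = 4, against 0.60 ± 0.21, SD, n = 7). In all, 2914 genes differed, 591 higher and 2323 lower (903 and 2028 after repeated quantile normalization, 1173 and 1793 with the upper quartile as a covariate). The median of all genes moved from -0.12 to -0.01 with that covariate. The count was 4442 without positive sample 2, and 1553, 1768 and 1818 without positive samples 3, 4 and 5. It was 4614 without the arrays whose upper quartile was under 6, 1639 with the replicate block and 1453 with blocks of neighbouring codes.

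In stomach, some Wnt target and stem cell genes rose in positive cells and several genes of acid-secreting cells fell. Wfdc18 rose by 5.75 (SE 0.83; 10.55 ± 0.32, SD, n = 3, against 4.79 ± 2.18, SD, n = 4), and Rgs5, a regulator of G protein signalling in pericytes, by 5.60 (SE 0.95). Cldn2 rose by 4.74 (SE 0.63), the major urinary protein Mup3 by 4.58 (SE 0.63) and the chloride channel Cftr by 4.53 (SE 0.48). The parietal cell nuclear receptor Esrrg (-4.23, SE 0.51), the cardiac troponin Tnni3 (-4.12, SE 0.83) and the potassium channel subunit Kcne2 (-4.09, SE 0.89) fell. Hamp2 (-3.75, SE 0.58) and Lpl (-3.65, SE 0.59) fell too. Of 23 epithelial stem and progenitor genes 7 rose and none fell (10 rose and 1 fell adjusted over the list alone; median 1.02, camera adjusted p = 1.4e-06, adjusted p = 0.0919 with an estimated correlation). These were Lgr5 (3.74), Cd44 (3.59), Ascl2 (3.13), Hopx (2.95), Smoc2 (2.59), Axin2 (1.54) and Prom1. Of 13 Wnt targets 4 rose (6 adjusted over the list alone; median 1.11, camera adjusted p = 1.8e-05, adjusted p = 0.0761 with an estimated correlation), among them the transcription factor Sp5 (2.48). In the gastric epithelium list the proton pump subunits Atp4a (-3.32) and Atp4b (-2.70) and the hormone gene Ghrl (-1.98) fell. Adjusted over the list alone 2 members rose and 3 fell. The median was above 0 (0.19) while the camera test pointed down, and the list was not called (adjusted p = 0.266). In all, 447 genes differed, 322 higher and 125 lower. The count was 1013 without negative sample 3, 799 without the negative sample numbered 2 with the higher upper quartile, 247 without the arrays whose upper quartile was under 6 and 184 with the replicate block. Without positive sample 2 the share called was 1.75% of 14081 genes, against 3.17%. A fit of the stomach samples alone called 0 (limma, 457 at an unadjusted p under 0.05). The calls of Tnni3 and Kcne2 were lost without positive sample 1 (adjusted p = 0.0532 and 0.077).

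In uterus, positive cells carried more macrophage, antigen presentation and epithelial transcripts and fewer stromal ones. Fcna rose by 5.56 (SE 0.94; 9.37 ± 1.02, SD, n = 4, against 3.80 ± 0.30, SD, n = 3) and Folr2 by 5.53 (SE 0.85). The Fc receptor-like gene Fcrls rose by 5.12 (SE 0.62), Ltc4s, which makes leukotrienes, by 4.97 (SE 0.85) and Cd209f by 4.90 (SE 0.94). Jchain (-4.33, SE 0.76), Gzmb (-4.15, SE 0.72), Iglv1 (-3.78, SE 0.85), Igk-V21 (-3.65, SE 0.70) and Il2rb (-3.62, SE 0.58) fell. Of 15 macrophage and monocyte genes 13 rose (15 adjusted over the list alone; median 3.42, camera adjusted p = 5.58e-15, adjusted p = 0.0712 with an estimated correlation), including the mannose receptor Mrc1 (4.20) and the growth factor receptor Csf1r (4.12). Of 8 MHC class II genes 5 rose (7 adjusted over the list alone; median 2.43, camera adjusted p = 2e-07, adjusted p = 0.0737 with an estimated correlation). Of 19 epithelial genes 8 rose (11 adjusted over the list alone; median 1.21, camera adjusted p = 6.53e-08, adjusted p = 0.0757 with an estimated correlation). Fibroblast and matrix genes fell in 10 of 16 cases (12 adjusted over the list alone; median -1.77, camera adjusted p = 1.83e-09, adjusted p = 0.0712 with an estimated correlation). Hedgehog targets fell in 3 of 5 cases (4 adjusted over the list alone; median -1.88, camera adjusted p = 5.3e-05, adjusted p = 0.0419 with an estimated correlation), namely the pathway's transcription factors Gli2 (-2.75) and Gli1 (-2.52) and its receptor Ptch1 (-1.88). Among uterine genes, Pax8 (2.47), Msx1 (2.06), the gland regulator Foxa2 (1.94) and Ihh (1.64) rose. Hoxa11 (-2.26), Hoxa10 (-2.0), the progesterone receptor Pgr (-1.40) and Emx2 (-0.96) fell (5 rose and 4 fell adjusted over the list alone). Uterine negative samples 1 and 2 were tilted further towards the 3' end (Gapdh 1.29 and 1.54, Actb 1.87 and 2.41) than any positive array (at most 0.88 and 1.02), and the effect on the calls was not tested. In all, 1541 genes differed, 747 higher and 794 lower. The count was 842 without negative sample 1, 971 without negative sample 2 and 2476 without the arrays whose upper quartile was under 6.

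The difference between positive and negative cells itself differed between tissues for 2982 of 14081 genes (limma moderated F test; 4501 without the stomach negative sample with the lowest upper quartile, 4523 without liver positive sample 2). The count was 1847 with blocks of neighbouring sample codes and 1110 with the replicate block by title number. Jchain, Igk-V21 and Iglv1 were called lower in 5 of the 6 tissues and 18 genes in at least 4, among them Gzmb, Gzma, Il2rb, Nkg7 and Icos. No gene was called higher in more than 3 tissues. The 12 called higher in 3 included Cd209f, Cd209g, Fcna, Folr2, Cd163, Ccl12, Wfdc15b, Sp5 and Prom1. Prostate and uterus shared 352 genes called lower where independent calls would give 47.5 (Fisher's exact adjusted p = 2.65e-237). Lung and uterus shared 32 genes called higher where independent calls would give 2.9 (Fisher's exact adjusted p = 4.77e-26). Liver and uterus shared 10 genes called higher where independent calls would give 31.4, with a correlation of -0.15 across genes, which are not independent replicates. The tissues shared a common estimate of the spread of each gene, so their calls were not independent to begin with. The Fisher p values treat genes as independent and do not measure agreement between samples.

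Tumours were compared with the normal cells of their organ, taken as the mean of both sorted groups, to ask what distinguishes each cancer from normal cells of the same organ. The tumours were frozen whole and the normal cells were dissociated and sorted, so the tumour state and the handling cannot be separated in any value of this comparison. Where the dimmer group lay under the median of its arrays, its level can be background, and the difference is then a lower bound. This held for 6 of 11 genes named in prostate, 3 of 11 in lung, 5 of 11 in liver, 7 of 11 in stomach and 5 of 11 in uterus. Averaged over 5 organs, immediate early transcription factors were lower in tumours. Fosb fell by 5.08 (SE 0.15, adjusted p = 8.38e-53). Atf3 (-3.75, SE 0.18), Fos (-3.73, SE 0.15), Nr4a3 (-3.48, SE 0.16), Nr4a1 (-3.17, SE 0.15), Jun (-2.82, SE 0.13) and Egr1 (-2.69, SE 0.17) fell too. So did Hpgd, which breaks down prostaglandins (-2.95), Retnla (-2.94) and the methyltransferase Inmt (-2.88). Genes higher in the mean with a difference above 0 in all 5 organs included matrix and matrix-associated proteins (Tnc 3.38, SE 0.22; Ccn2 3.34, SE 0.21; Ltbp2 2.88, SE 0.21) and the chitinase-like protein Chil3 of activated macrophages (3.64, SE 0.33). Among them were also the cornified envelope protein Ivl (3.11, SE 0.27), Wfdc2 (3.04), Ajuba (2.99, SE 0.14), the oxygen sensor Egln3 (2.90), Irx3 (2.77) and the noncoding transcript Gt(ROSA)26Sor (2.75). In lung Tnc, Ccn2 and Chil3 differed by only 0.10, 0.18 and 0.24, and in liver Ivl by 0.18.

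Of 17 immediate early and dissociation genes 16 were lower in tumours on average (16 adjusted over the list alone; median -2.25, camera adjusted p = 9e-22, adjusted p = 0.000437 with an estimated correlation). Of 23 cell cycle genes 20 rose and none fell (20 adjusted over the list alone; median 0.99, camera adjusted p = 4.89e-05, adjusted p = 0.63 with an estimated correlation). The cell cycle list was not called in lung (2 rose and 2 fell, 1 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 0.986) or stomach (1 rose and 2 fell; median -0.15, camera adjusted p = 0.573). All 19 epithelial genes rose (19 adjusted over the list alone; median 1.0, camera adjusted p = 1.19e-05, adjusted p = 0.318 with an estimated correlation). In stomach the epithelial list went the other way, with 10 members lower and 3 higher (10 and 3 adjusted over the list alone; median -0.84, camera adjusted p = 0.0289, adjusted p = 0.691 with an estimated correlation). T and NK cell genes fell in 13 of 15 cases (median -0.87, camera adjusted p = 5.16e-06, adjusted p = 0.283 with an estimated correlation). Where a tumour list is given with 1 count, the count adjusted over the list alone was the same. By limma, 9644 of 14663 genes differed on average, 5717 higher and 3927 lower. Of these, 3313 had the same sign in all 5 organs, 1976 higher and 1337 lower. With the upper quartile as a covariate the split was 2933 higher and 3990 lower, and the median of all genes moved from 0.08 to -0.04. The tumour difference itself differed between organs for 11422 genes.

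**Figure D4:**
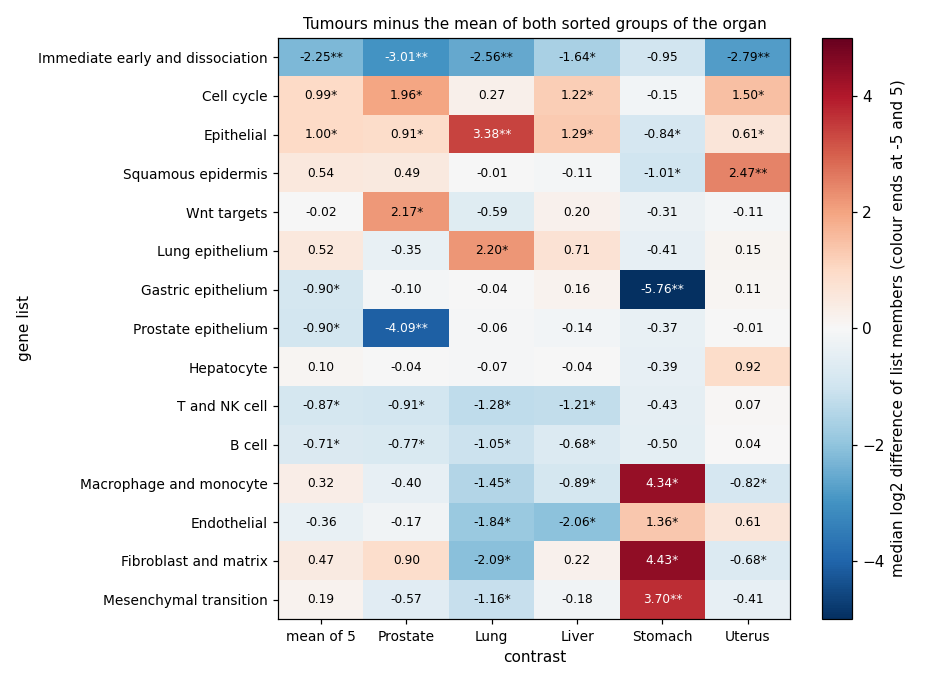
Median log2 difference, tumour minus sorted normal cells, of 15 fixed gene lists in the mean of 5 organs and in each organ; asterisks as for the sorted cells, with colours ending at -5 and 5. The immediate early median is -2.25 in the mean, and the gastric epithelium median is -5.76 in stomach.

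In prostatic adenocarcinomas, secretory products of the prostate were lower in most tumours and Wnt targets were higher. Sbp, the spermine-binding protein of prostate secretion, fell by 8.56 (SE 0.68). The trypsin inhibitor Spink1 (-7.64, SE 0.89), Fosb (-7.29, SE 0.35), Pate4 (-7.08, SE 0.61) and Scgb2b27 (-6.47, SE 0.32) fell too. Sbp averaged 4.69 ± 4.25 (SD, n = 10) in tumours, against 13.27 ± 0.20 (SD, n = 8). Some tumours kept these products, with Sbp above the upper quartile of the array in 2 of 10, Spink1 in 3 and Pate4 in 4. The defensin Defa21 rose by 7.60 (SE 0.33; 10.41 ± 0.75, SD, n = 10, against 2.79 ± 0.29, SD, n = 8) and Prr9 by 7.39 (SE 0.52). The hair follicle protein Tchh rose by 7.03 (SE 0.32), the cornified envelope gene Sprr2h by 6.06 (SE 0.49) and the crystallin Cryba4 by 5.60 (SE 0.37). The squamous epidermis list was not called (4 of 16 rose and 1 fell, 3 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.206). Of 10 prostate epithelium genes 9 fell (9 adjusted over the list alone; median -4.09, camera adjusted p = 7.62e-13, adjusted p = 2.22e-06 with an estimated correlation). Of 17 immediate early genes 16 fell (median -3.01, camera adjusted p = 1.79e-20, adjusted p = 0.000377 with an estimated correlation). Of 13 Wnt targets 10 rose (median 2.17, camera adjusted p = 9.61e-08, adjusted p = 0.0781 with an estimated correlation), including the Wnt pathway regulators Dkk2 (5.61), Apcdd1 (4.39) and Axin2 (2.44). Of 23 cell cycle genes 20 rose (median 1.96, camera adjusted p = 3.32e-12, adjusted p = 0.366 with an estimated correlation). Of 9 smooth muscle genes 8 rose (median 2.24, camera adjusted p = 0.0002, adjusted p = 0.465 with an estimated correlation). Prom1 did not differ (-0.26, SE 0.81, adjusted p = 0.841). Its difference was 0.05 with array weights and 0.62 against negative cells alone. In all, 5385 genes differed, 3062 higher and 2323 lower (2070 and 2760 with the upper quartile as a covariate).

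In bronchial papillary adenomas, epithelial genes were higher and immediate early genes lower than in sorted lung cells. The potassium channel Kcnk1 rose by 6.10 (SE 0.48; 9.71 ± 0.42, SD, n = 14, against 3.77 ± 0.60, SD, n = 10) and the transcription factor Elf5 by 5.69 (SE 0.29). The iron-siderophore carrier Lcn2 rose by 5.67 (SE 0.44), Mal by 5.64 (SE 0.55) and Egfl6 by 5.64 (SE 0.39). The neutrophil chemokine Cxcl2 (-7.36, SE 0.64), the cytokine Il6 (-6.6, SE 0.41) and the monocyte chemokine Ccl7 (-5.65, SE 0.44) fell, as did Atf3 (-5.80, SE 0.37) and Fosb (-5.68, SE 0.31). Of 19 epithelial genes 17 rose (18 adjusted over the list alone; median 3.39, camera adjusted p = 3.01e-19, adjusted p = 0.00763 with an estimated correlation). Of 13 lung epithelium genes 9 rose (median 2.20, camera adjusted p = 8.14e-06, adjusted p = 0.0549 with an estimated correlation). All 17 immediate early genes fell (median -2.56, camera adjusted p = 2.8e-19, adjusted p = 0.00125 with an estimated correlation). Endothelial genes fell in 12 of 15 cases and rose in 1 (13 and 1 adjusted over the list alone; median -1.84, camera adjusted p = 4.94e-06, adjusted p = 0.326 with an estimated correlation). Fibroblast and matrix genes fell in 12 of 16 cases (median -2.09, camera adjusted p = 8.14e-06, adjusted p = 0.241 with an estimated correlation) and macrophage and monocyte genes in 9 of 15 (median -1.45, camera adjusted p = 0.00498, adjusted p = 0.674 with an estimated correlation). In all, 6315 genes differed, 3425 higher and 2890 lower. Prom1 did not pass (-0.16, SE 0.73, adjusted p = 0.898).

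In hepatocellular carcinomas, Prom1 was higher than in sorted liver cells by 4.94 (SE 0.70; 7.99 ± 1.99, SD, n = 13, against 3.02 ± 0.48, SD, n = 11; adjusted p = 5.55e-09). The level in sorted cells lay under the array medians, so the difference is at least of this size if that level is background. Lcn2 rose by 7.28 (SE 0.42), the sulfotransferase Sult2a2 by 6.65 (SE 0.41), the retinol dehydrogenase Rdh9 by 4.77 (SE 0.44), the protease Prss8 by 3.92 (SE 0.33) and Egln3 by 3.85 (SE 0.39). Mup3 (-8.5, SE 0.61) and the steroid dehydrogenase Hsd3b5 (-7.28, SE 0.18) fell. So did 3 genes of liver sinusoidal cells or vessels, Dnase1l3 (-5.51, SE 0.33), Clec4g (-4.94, SE 0.44) and Wnt2 (-4.72, SE 0.40). Of 15 endothelial genes 12 fell (13 adjusted over the list alone; median -2.06, camera adjusted p = 2.42e-08, adjusted p = 0.454 with an estimated correlation). T and NK cell genes fell in 13 of 15 cases (median -1.21, camera adjusted p = 1.86e-05, adjusted p = 0.454 with an estimated correlation) and MHC class II genes in 7 of 8 (median -1.18, camera adjusted p = 0.00401, adjusted p = 0.727 with an estimated correlation). Macrophage and monocyte genes fell in 8 of 15 cases and rose in 1 (median -0.89, camera adjusted p = 0.00401, adjusted p = 0.892 with an estimated correlation). Of 9 cholangiocyte genes 6 rose (median 1.77, camera adjusted p = 0.0204, adjusted p = 0.517 with an estimated correlation), including the duct transcription factor Sox9 (2.88), Pkhd1 (2.49) and Anxa13 (2.42). Of 23 cell cycle genes 16 rose (18 adjusted over the list alone; median 1.22, camera adjusted p = 0.00301, adjusted p = 0.934 with an estimated correlation). Immediate early genes fell in 14 cases and rose in 2 (median -1.64, camera adjusted p = 1.95e-08, adjusted p = 0.169 with an estimated correlation). The hepatocyte list was not called (1 of 18 genes fell and 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.687). In all, 6921 genes differed, 4285 higher and 2636 lower (2600 and 2831 with the upper quartile as a covariate).

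In gastric adenocarcinomas, the products of mature gastric glands were lower and mesenchymal, matrix and macrophage genes were higher. The hormone gene Gast fell by 9.10 (SE 0.33). The pepsinogen Pgc (-8.79, SE 0.30), the intrinsic factor gene Cblif (-8.69, SE 0.33), the colipase Clps (-8.28, SE 0.40) and the chitinase Chia1 (-7.76, SE 0.60) fell too. Gast averaged 2.69 ± 0.29 (SD, n = 11) in tumours, under the array medians, and 11.64 ± 1.82 (SD, n = 7) in sorted cells. Ccn2, a matrix signalling protein, rose by 8.55 (SE 0.48), Chil3 by 7.90 (SE 0.77), Tm4sf1 by 7.74 (SE 0.41), the thrombin receptor F2r by 7.43 (SE 0.39) and the collagen Col5a2 by 7.21 (SE 0.45). Of 14 gastric epithelium genes 12 fell (13 adjusted over the list alone; median -5.76, camera adjusted p = 1.73e-15, adjusted p = 0.00538 with an estimated correlation). Of 11 mesenchymal transition genes 9 rose (9 adjusted over the list alone; median 3.70, camera adjusted p = 1.7e-07, adjusted p = 0.0247 with an estimated correlation), including fibronectin Fn1 (6.71) and vimentin Vim (6.62). All 15 macrophage and monocyte genes rose (median 4.34, camera adjusted p = 7.72e-11, adjusted p = 0.164 with an estimated correlation). Of 16 fibroblast and matrix genes 13 rose (median 4.44, camera adjusted p = 4.87e-08, adjusted p = 0.164 with an estimated correlation). Endothelial genes rose in 10 of 15 cases (median 1.36, camera adjusted p = 0.0397, adjusted p = 0.716 with an estimated correlation) and smooth muscle genes in 6 of 9 (median 1.61, camera adjusted p = 0.0289, adjusted p = 0.691 with an estimated correlation). Array quality differed with this contrast: the upper quartile averaged 5.90 and 5.92 in the positive and negative cells against 6.48 in tumours, and the Actb ratio of 3' to 5' probe sets 1.22 and 1.44 against 0.57. Immediate early genes fell in 9 cases and rose in 4, and the list was not called (median -0.95, camera adjusted p = 0.0732). Prom1 fell by 3.19 (SE 0.81, adjusted p = 0.000478). It averaged 7.84 in tumours, with values from 3.39 to 11.29. The mean was 10.2 in negative cells and 11.9 in positive cells, which had been selected for Prom1. In all, 8514 genes differed, 5135 higher and 3379 lower, against 3829 and 4276 after repeated quantile normalization and 2417 and 3847 with the upper quartile as a covariate. The median of all genes was 0.11, and -0.07 and -0.12 under those settings.

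In uterine adenocarcinomas, keratins and other genes of stratified epithelium rose and some uterine genes fell. The water channel Aqp4 rose by 5.96 (SE 0.73; 9.37 ± 1.54, SD, n = 9, against 3.44 ± 0.62, SD, n = 7) and Hba-a1 by 5.65 (SE 0.54). The hemidesmosome collagen Col17a1 rose by 5.43 (SE 0.49), Col8a1 by 5.2 (SE 0.54) and Hbb-b2 by 4.98 (SE 0.56). Fosb (-7.64, SE 0.37), the collagen Col6a4 (-6.67, SE 0.23), Prap1 (-6.31, SE 0.80), the glucocorticoid-inactivating enzyme Hsd11b2 (-6.25, SE 0.34) and Inmt (-5.78, SE 0.71) fell. Of 16 squamous epidermis genes 11 rose (11 adjusted over the list alone; median 2.47, camera adjusted p = 2.55e-11, adjusted p = 0.0102 with an estimated correlation), including the basal keratins Krt14 (6.88) and Krt5 (5.68) and Krt6a (5.90). Of 5 Hedgehog targets 4 fell (median -1.65, camera adjusted p = 3.11e-05, adjusted p = 0.0102 with an estimated correlation), led by Gli1 (-3.56). All 17 immediate early genes fell (median -2.79, camera adjusted p = 3.11e-32, adjusted p = 6.78e-06 with an estimated correlation). In the uterine list 5 of 11 genes fell (7 adjusted over the list alone; median -1.04, camera adjusted p = 0.000113, adjusted p = 0.091 with an estimated correlation), including Pgr (-3.83) and Hoxa10 (-3.76). All 8 MHC class II genes fell (median -1.5, camera adjusted p = 4.12e-05, adjusted p = 0.257 with an estimated correlation). Of 23 cell cycle genes 17 rose (19 adjusted over the list alone; median 1.5, camera adjusted p = 5.98e-07, adjusted p = 0.611 with an estimated correlation). Prom1 fell by 3.70 (SE 0.85, adjusted p = 0.000324). Its mean was 6.94 in tumours, against 9.91 in negative cells and 11.37 in positive cells, which had been selected for Prom1. In all, 4226 genes differed, 2410 higher and 1816 lower.

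Whether tumours resembled the Prom1-positive cells of their organ more than the Prom1-negative ones bears on the origin named in the series title. For each tumour the Pearson r across genes with the mean profile of the negative cells was subtracted from that with the mean profile of the positive cells. The mean difference was 0.0136 ± 0.0217 (SD, n = 10 tumours) in prostate, where r averaged 0.845 and 0.832, and -0.0148 ± 0.00763 (SD, n = 14) in lung. It was 0.0149 ± 0.0259 (SD, n = 13) in liver, 0.00355 ± 0.00482 (SD, n = 11) in stomach and 0.0173 ± 0.0254 (SD, n = 9) in uterus. The mean over all relabellings was -0.00541 in prostate, -0.00664 in lung, -0.00567 in liver, -0.00473 in stomach and 0.00297 in uterus. A cut at 0 does not take this into account, and all tumours of an organ shared the same mean profiles. With that cut the tumour was closer to the positive profile in 6 of 10 prostatic, 0 of 14 lung, 9 of 13 liver, 8 of 11 gastric and 7 of 9 uterine tumours. These numbers depended on single normal samples. In stomach they were 1 of 11 without positive sample 1, 2 without positive sample 3 or the negative sample with the lowest upper quartile, and 11 without any 1 of the other 4 samples. In liver the number was 5 of 13 without positive sample 2. No difference passed the exact two-sided permutation of the sort labels (p = 0.161, 0.283, 0.339, 0.771 and 0.171; adjusted over the 5 organs 0.424, 0.424, 0.424, 0.771 and 0.424). The smallest p that the relabellings allow is 0.0179, 0.00833, 0.00303, 0.0286 and 0.0286. The relabellings ignored the pairs of neighbouring sample codes, whose correlations reached 0.494 in liver and 0.386 in uterus. Over the 1000 genes of largest variance among normal cells, the lung difference was -0.0362 and the prostate difference turned to -0.0409 (exact adjusted p = 0.0446 for both). The lung difference was -0.036 without positive sample 1 (exact p = 0.0278). Without positive sample 4, whose upper quartile was under 6, it was -0.012, against a mean of -0.0116 over the relabellings (exact p = 0.944).

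**Figure D5:**
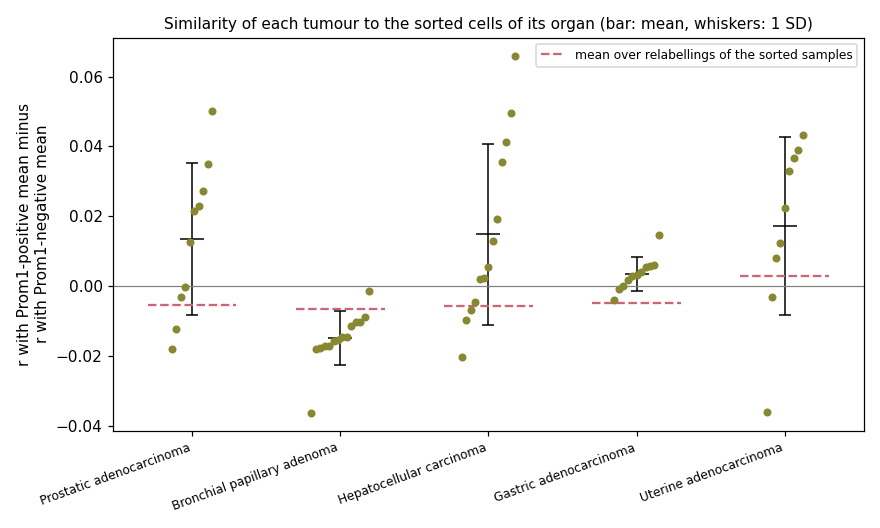
Difference in Pearson r across genes (r with the Prom1-positive mean minus r with the Prom1-negative mean) for each tumour by organ, with the mean and 1 SD; the dashed lines give the mean over all relabellings of the normal samples. All 14 lung tumours lie below 0, and the other 4 organs hold tumours on both sides.

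The 7 tumour types were compared with one another to see whether each kept the genes of its tissue. Of 13456 genes, 12801 differed among types (limma moderated F test). Each difference is the type's mean minus the mean of the other 6 types. Where the mean of the other types lay under the array medians, it can be background, and the difference is then a lower bound. Surfactant genes marked the bronchial adenomas (Sftpc 10.82, SE 0.48; Sftpa1 10.37, SE 0.34; the alveolar cell receptor Ager 8.33, SE 0.34). In them all 13 lung epithelium genes rose (13 adjusted over the list alone; median 5.24, camera adjusted p = 4.32e-17, adjusted p = 0.000137 with an estimated correlation). Plasma protein genes marked the hepatocellular carcinomas (Fgb 10.10, SE 0.40; Apoa2 9.82, SE 0.37; Hpx 9.78, SE 0.42). All 18 hepatocyte genes rose (18 adjusted over the list alone; median 8.64, camera adjusted p = 7.91e-21, adjusted p = 0.0112 with an estimated correlation). Prostatic adenocarcinomas were marked by Prr9 (9.15, SE 0.42), Defa21 (7.76, SE 0.12) and the prostate homeobox gene Hoxb13 (6.21, SE 0.20). In them 7 of 10 prostate epithelium genes rose (8 adjusted over the list alone; median 2.80, camera adjusted p = 7.51e-08, adjusted p = 0.00128 with an estimated correlation). Of 13 Wnt targets 12 rose (12 adjusted over the list alone; median 3.71, camera adjusted p = 4.02e-16, adjusted p = 0.00733 with an estimated correlation), among them Wif1 (5.77), Apcdd1 (5.56), Dkk2 (5.49), Tbx3 (5.12), Axin2 (4.13) and Lgr5 (2.58). Skin carcinomas were marked by keratins and a cystatin (Krt6b 9.42, SE 0.43; Krt13 8.56, SE 0.45; Csta1 8.55, SE 0.51). All 16 squamous epidermis genes were higher (16 adjusted over the list alone; median 6.11, camera adjusted p = 2.72e-28, adjusted p = 3.93e-05 with an estimated correlation).

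Lymphomas were marked by Gimap7 (7.31, SE 0.38), the interferon-induced chemokine Cxcl9 (7.28, SE 1.02) and Tnfrsf13c, the receptor for the B cell survival factor BAFF (7.0, SE 0.35). Of 12 B cell genes 11 rose (11 adjusted over the list alone; median 4.76, camera adjusted p = 3.4e-13, adjusted p = 0.00631 with an estimated correlation). Of 15 T and NK cell genes 13 rose as well (14 adjusted over the list alone; median 4.5, camera adjusted p = 4.26e-16, adjusted p = 0.00631 with an estimated correlation). Gastric adenocarcinomas were marked by Plaur, the urokinase receptor (2.67, SE 0.28), and Ankrd50 (2.34, SE 0.14). Of their 13 gastric epithelium genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 2.12, camera adjusted p = 0.00502, adjusted p = 0.404 with an estimated correlation). Gkn3, Gkn1, Tff2, Tff1, Gkn2, Ctse and Muc5ac, products of surface and neck mucous cells, rose and Chia1 fell, while the parietal cell genes Atp4a and Atp4b differed by 0.07 and 0.05. No gene of the uterine adenocarcinomas met the rule for naming. In them 7 of 11 uterine genes rose (7 adjusted over the list alone; median 1.24, camera adjusted p = 3.02e-05, adjusted p = 0.101 with an estimated correlation), including Emx2 (4.38), Msx1 (3.59) and Pgr (2.97). With 3 lymphomas the values of that type rest on the fewest arrays.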

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

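Chosen only after their results had been seen were the test of the Prom1 transcript in lung, the test of immediate early genes against either sorted group and the fit with the upper quartile as a covariate.

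A sample stood far from the others of its group in 2 of 22 tests of groups of 4 to 10 samples, where chance gives about 1 in 20. The upper quartile of the array was 6.05 in prostate Prom1-negative sample 1, whose nearest neighbour was at 6.41, a gap of 0.91 of the group's range. It was 6.08 in lung Prom1-negative sample 2, with the nearest at 6.40 and a gap of 0.869 of the range.

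Of the 20 genes named for the mean of 6 tissues and Prom1, 14 changed by amounts that differed between tissues. The interaction adjusted p was 0.00171 for Cd209f, 4.91e-05 for Wfdc15b, 0.00128 for Cldn2, 0.00531 for Trem2, 0.000689 for Mia, 0.00712 for Gzmb, 0.00578 for Hbb-b2, 0.00147 for Jchain, 0.00724 for Hba-a1, 0.0351 for Igk-V21, 0.0247 for Iglv1, 0.00745 for Cd3g, 0.0132 for Ctsw and 0.0322 for Prom1. The sort difference of Jchain was -5.57 in prostate and -0.28 in stomach, and Cldn2 was 4.74 higher in stomach and 0.35 in lung.

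Of the 20 genes named for the mean of 5 organs and Prom1, 20 changed by amounts that differed between organs. The interaction adjusted p was 1.46e-08 for Chil3, 7.26e-15 for Tnc, 5.78e-20 for Ccn2, 1.45e-05 for Ivl, 0.00547 for Wfdc2, 4.68e-07 for Ajuba, 1e-07 for Egln3, 6.66e-09 for Ltbp2, 2.53e-09 for Irx3, 0.000239 for Gt(ROSA)26Sor, 2.42e-24 for Fosb, 1.01e-12 for Atf3, 0.0301 for Fos, 2.06e-22 for Nr4a3, 7.6e-09 for Nr4a1, 0.000861 for Hpgd, 3.89e-07 for Retnla, 1.27e-07 for Inmt, 0.000298 for Egr1 and 1.16e-11 for Prom1. Prom1 was 4.94 higher in liver tumours, a lower bound if the dim level in sorted liver cells is background, and 3.70 lower in uterine ones (-3.70). Jun did not pass (0.0832).

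Several scavenger receptor and resident macrophage genes were among the largest rises in Prom1-positive cells of lung and uterus, and Cd209f was also higher in prostate (3.01). With an estimated correlation the macrophage and monocyte list was not called in lung or uterus. A candidate explanation for these rises is that macrophages were carried into the positive fraction, since the labels name no step that removes leukocytes. Of 15 other resident macrophage genes, none among the fixed lists, 8 rose in uterus with a median of 1.77. Folr2 stood at 10.59 and Fcna at 9.37 in the positive cells. Most genes of the macrophage and monocyte list had already risen in the same arrays, so such a rise was likely beforehand. It shows macrophage RNA in the positive fraction but cannot tell carry-over from macrophages that themselves carry Prom1. In lung 1 rose, Timd4, with a median of 1.09, and in prostate none rose and Igf1 fell, with a median of 0.70. Carry-over stays open in lung and prostate as well. In lung Prom1 itself differed by 0.01 with an upper bound of 0.782, which leaves open whether a modest enrichment of Prom1-expressing cells went along with it, and macrophages that themselves carry Prom1 were not tested.

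Leukocyte and endothelial genes were lower in Prom1-positive liver cells, whose arrays were also of lower quality. The camera calls of their lists were lost with an estimated correlation. The T and NK cell, macrophage and monocyte, and endothelial medians (-2.32, -2.44 and -1.82) lay at percentile 0 of 10000 random lists matched for expression, where 95% of medians for the T and NK cell list fell between -0.56 and 0.21. With the upper quartile in the model the medians were -2.24, -2.36 and -1.64. The random lists drew genes singly, so they did not carry the correlation between genes of a list. The covariate took in the upper quartile alone. The 3' tilt of the positive arrays (Gapdh 1.14 against 0.60 in negative ones) was in neither test. The falls thus remained with the upper quartile in the model, but a wider effect of array quality cannot be excluded. A larger share of hepatocytes in the positive fraction stays open and was not tested separately, though the hepatocyte median of 0.42 lay at percentile 99.9 of its random lists while none of its 18 genes passed.

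Immediate early genes were lower in tumours than in sorted cells. A candidate explanation is a response of the normal cells to dissociation and sorting, which the tumours did not undergo. The list median was below 0 in all 5 organs against either sorted group, with the highest at -0.60 in stomach against negative cells, where 8 genes fell and 5 rose. No normal tissue was frozen whole among the samples compared, so handling and the tumour state cannot be told apart.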

How the results depend on the processing

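The settings that leave out arrays with an upper quartile under 6, add the upper quartile as a covariate or leave out the stomach negative sample with the lowest upper quartile were chosen after the data were seen. Unless a sentence gives a cause, the cause was not tested. All 16 counts stayed within 1.5 times their value with averaged probe sets, no filter on dim genes, a stricter filter, median centring or trended and robust eBayes, as did the 15 counts with a term for sample code range, the 5 from single-organ fits and the 7 under each single normal reference. Of 175 named gene values, 175 kept direction and call under repeated quantile normalization and all but 1 with averaged probe sets. Fits of 1 tissue alone lost 17 of 60 calls of named genes, the replicate block by title number lost 10 of 82 and the fit of all 117 samples lost 5 of 82. Blocks of neighbouring sample codes lost 2 of 76, Ms4a4b in lung (limma adjusted p = 0.107) and Prom1 in uterus (limma adjusted p = 0.114). Of 186 list results those blocks lost 2 calls and gained 8. With an estimated correlation 444 of 620 list results kept their call and 176 lost it. With fry 491 kept theirs, 16 lost it and 113 gained one. With a replicate block by title number 694 genes were called in the sort mean, 523 in prostate, 56 in lung, 0 in intestine (limma, 1.14% of genes at an unadjusted p under 0.05), 1639 in liver, 184 in stomach and 1110 in the interaction. That block turned the immediate early list in intestine (adjusted p = 0.923) and the cell cycle list in lung (adjusted p = 0.0483). Blocks of neighbouring codes gave 1.0e+02 in lung (0.731% of genes), 1453 in liver and 1847 in the interaction, and no value in intestine, which has no such pairs.

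With every probe tested there were more tests: 3.4e+02 called in lung (1.48% of probe sets), 4544 in liver, and for tumours 15698 in the mean, 8486 in prostate, 9983 in lung, 11253 in liver, 13672 in stomach, 6731 in uterus, 18180 in the interaction and 20264 among types. Array weights gave 5612 in the sort mean, 4045 in prostate, 1014 in lung, 462 in intestine, 4961 in liver, 5951 in uterus, 8696 in the interaction, 8104 in prostate tumours and 6777 in uterine tumours, and turned Prom1 in prostate tumours to 0.0487. Repeated quantile normalization gave 854 in stomach. All 117 samples in the fit gave 64 in intestine and 852 in stomach. Fits of 1 tissue alone, with fewer samples, gave 2304 in prostate, 57 in lung, 2 in intestine, 0 in stomach (limma, 457 at an unadjusted p under 0.05) and 3197 in uterus.

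Without arrays with an upper quartile under 6 there were 2424 in prostate, 46 in intestine, 4614 in liver, 247 in stomach, 2476 in uterus and 5244 in the interaction, the stomach similarity was -0.00545, and the squamous epidermis list in stomach turned (adjusted p = 0.019). The covariate gave 3447 in the sort mean, 1991 in prostate and 1389 in stomach, turned Prom1 in lung to -0.0355, and moved the median of all genes in lung from -0.01 to 0.10. The code range term turned it to -0.0163. Without the stomach negative sample with the lowest upper quartile there were 3068 in the sort mean and 4501 in the interaction, and the stomach similarity was -0.00258. Against negative cells alone the tumour difference of Prom1 was 0.617 in prostate and 0.0359 in the mean. The similarity over 1000 genes was -0.0409 in prostate and -0.0362 in lung. In stomach it was -0.000128 by Spearman and -0.0458 as a projection.

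Leaving out each sample in turn gave 1593 to 3068 genes in the sort mean, 656 to 1521 in prostate (lowest without positive sample 2), 120 to 526 in lung (without positive samples 4 and 1; 124 without 2), 14 to 68 in intestine (without positive samples 3 and 2; 50 and 47 without negative samples 1 and 2), 1553 to 4442 in liver (without positive samples 3 and 2; 1768 and 1818 without 4 and 5), 2.5e+02 (1.75% of genes) to 1013 in stomach (without positive sample 2 and negative sample 3; 799 without the other negative sample numbered 2), 842 to 1472 in uterus (lowest without negative sample 1; 971 without 2) and 2312 to 4523 in the interaction (highest without liver positive sample 2; 4501 without the stomach negative sample with the lowest upper quartile). The 8 tumour counts moved less than 1.5 times. Similarity ranged from 0.00622 to 0.0231 in prostate, -0.036 (without positive sample 1, exact p = 0.0278) to -0.0107 in lung, -0.000957 (without positive sample 2) to 0.0201 in liver, -0.00735 to 0.0178 in stomach (below 0 without positive sample 1 or 3 or the negative sample with the lowest upper quartile) and 0.00943 to 0.0368 in uterus. Prom1 ranged from -0.0969 (without lung negative sample 2) to 0.145 in lung cells, -0.0994 (without positive sample 5) to 0.428 in liver cells and -0.344 to 0.0128 (above 0 without adenoma 3 or 12) in lung tumours; none of these 3 was called. The contrasts of 1 tissue within the joint fit recovered 16% to 30% of simulated changes of 1.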

Other observations

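Every count of other splits, and the comparison with splits that part neighbouring sample codes, was chosen after the real count had been seen.

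Transcripts that report MAPK signalling were higher in tumours of stomach and lung. The list was not called in prostate (3 of 13 rose and 1 fell, 3 and 1 adjusted over the list alone; camera adjusted p = 0.624), liver (4 rose and 1 fell, 3 and 1 adjusted over the list alone; camera adjusted p = 0.687) or uterus (3 rose and 4 fell, 3 and 4 adjusted over the list alone; camera adjusted p = 0.614). In gastric adenocarcinomas 11 of 13 MAPK feedback genes rose and none fell (11 adjusted over the list alone; median 1.90, camera adjusted p = 0.00127, adjusted p = 0.482 with an estimated correlation), led by the phosphatase Dusp4 (3.18), Ier3 (3.01), the AP-1 member Fosl1 (2.66) and the signalling inhibitor Spry4 (2.51). In bronchial adenomas 9 rose and 2 fell (9 and 2 adjusted over the list alone; median 1.32, camera adjusted p = 0.0207, adjusted p = 0.558 with an estimated correlation): the transcription factor Etv5 (3.54) and the inhibitor Spry2 (2.19) rose by the largest amounts, and Ier3 (-2.52) and Fosl1 (-1.02), which also respond to acute stimulation, fell. In the mean of 5 organs 9 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.76, camera adjusted p = 0.0329, adjusted p = 0.63 with an estimated correlation). All 8 MHC class II genes, which present antigen to helper T cells, fell in the same mean (8 adjusted over the list alone; median -0.66, camera adjusted p = 0.0177, adjusted p = 0.63 with an estimated correlation), among them H2-Eb1 (-0.89), Cd74 (-0.75) and the regulator Ciita (-0.33). This did not hold in stomach, where 5 rose and none fell (5 adjusted over the list alone; median 1.88, camera adjusted p = 0.168), or in lung, where 1 rose and 1 fell (1 and 1 adjusted over the list alone; median -0.03, camera adjusted p = 0.836).

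Tumour types differed in proliferation genes. In bronchial papillary adenomas 22 of 23 cell cycle genes were lower than in the other types (22 adjusted over the list alone; median -1.72, camera adjusted p = 4.74e-09, adjusted p = 0.539 with an estimated correlation), including Top2a (-2.40) and Mki67 (-1.64). In lymphomas 21 were higher and none lower (23 adjusted over the list alone; median 1.96, camera adjusted p = 3.11e-06, adjusted p = 0.57 with an estimated correlation), including Mki67 (2.54) and Cdc6 (2.66), both parts of dividing cells. The Prom1 transcript varied widely within some types: it averaged 6.03 ± 3.18 (SD, n = 6) in skin carcinomas, 6.94 ± 3.24 (SD, n = 9) in uterine adenocarcinomas with values from 2.45 to 10.67, and 3.91 ± 0.91 (SD, n = 3) in lymphomas.

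Other splits of the same samples, taken as independent, were counted to see if chance can be excluded. For the Prom1 sort it can for the mean of 6 tissues, where 1 of 100 splits, the real one, gave as many genes (1917, highest other 535), for prostate (1 of 56; 1294, highest other 739) and for the interaction (1 of 100; 2982, highest other 1095). It cannot be excluded for lung (6 of 100; 212, highest other 654), intestine (4 of 56; 28, highest other 59) or stomach (14 of 35; 447, highest other 4558). In stomach and lung the split with the most genes called several times the real count, which points to a sample structure of untested nature. These splits left out the pairs of neighbouring sample codes, which correlated above 0.1 in 3 of 3 cases in liver and in uterus. In liver 3 of 100 splits gave as many genes (2914, highest other 3997), but of the 40 splits that part all 3 pairs 3 did (highest other 3997), so chance cannot be excluded there. Both other splits with as many genes differed from the real one only by exchanging positive sample 2 with negative sample 3 or 6. In uterus 8 splits part all 3 pairs, too few for a share under 0.05 (1541, highest other 162; 620 among all 35 splits). In prostate and lung 2 of 3 pairs correlated above 0.1. In each, 8 splits part the pairs, also too few (highest other 624 and 4). In prostate chance is excluded only over splits that leave the pairs out. With splits that part the pairs of liver and uterus, 1 of 100 gave as many genes in the mean of 6 tissues (highest other 318) and 1 of 100 in the interaction (highest other 2016). For tumours 1 of 100 splits, the real one, gave as many genes in 8 counts (highest other in brackets). These were 9644 (483) in the mean of 5 organs, 5385 (4317) in prostate, 6315 (1779) in lung and 6921 (3106) in liver. They were 8514 (6721) in stomach, 4226 (1291) in uterus, 11422 (1238) in the interaction and 95.1% (2.03%) of 13456 genes among types. If samples are independent, chance can be excluded for these.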
